A study of Mus musculus with 13 samples.

How the data were processed

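Whole-kidney poly(A) RNA of NZB/W F1 mice was sequenced in 9 libraries, 3 for each age (10, 20 and 30 weeks), and 4 sections of 30-week kidney were measured on Visium slides. The bulk values are raw read counts per gene symbol as the authors deposited them, made with bcl2fastq 2.20.0, STAR 2.7.8a and HTSeq 2.0.1 on GRCm38 (mm10), per the submitters' processing notes. The strand setting and the gene annotation of the counting are not given in the sources used here, so antisense and overlapping genes such as Frmd8os, and members of multigene families such as Saa1, Cyp2d12, Iglc1, the H2 genes and the haemoglobin genes, are uncertain. The authors also deposited a table with regularised log2 values and a log2 fold change of 30 over 10 weeks with p-values, made with DESeq2 1.40.2 per the submitters' processing notes; its log2 fold changes, p-values and adjusted p-values were compared with the calls made here. For the sections, the deposited values are counts of unique molecules (UMIs) per gene and spot under tissue from Space Ranger 2.0.0, per the file headers. A score per gene and section, Moran's I, and its adjusted p-value were also deposited by the authors, from Space Ranger per the file headers, and were used only to rank genes within a section.

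Between 32.3 and 36.4% of all counted bulk reads were assigned to a gene, 44.7 to 48.4% to no gene, 17.7 to 20.5% were not uniquely placed and 0.195 to 0.267% were ambiguous; only the first were used. The bulk libraries held 28776366 to 39344693 gene reads and the sections 6157933 to 15501138 UMIs. Between replicates of one age the chi-squared statistic per degree of freedom was 16.9 to 88.8, so counting error was a small part of the spread. Intervals and floors cover counting error only.

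Bulk counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3; TMM scaling, filterByExpr), with all 9 libraries in one fit, and p-values were adjusted by Benjamini and Hochberg's method over the 15706 genes tested; genes passed at an adjusted p under 0.05. Every adjusted p for a gene comes from edgeR unless another tool is named. The comparisons were each pair of ages, any difference among the 3 ages, and the change in the later interval less that in the earlier one. Gene lists, 43 in all, were tested with camera in limma 3.58.1 with the correlation between genes preset to 0.01, where at least 5 genes were tested, adjusted over all lists and the 3 pairs of ages or the 3 spatial comparisons. Each list test was repeated with an estimated correlation and with fry. Immunoglobulin and T cell receptor constant genes including Igkc were not analysed here in bulk.

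Spots with at least 500 UMIs were kept. Markers were taken as the logarithm of 1 plus counts per 10000 and standardised within each section, and a spot's score was the mean over the markers of a region. Medulla zone spots had a medulla minus cortex score above 0.5, cortex zone spots below -0.5, and spots between were left out. Glomerular spots were the highest 10% of cortex zone spots and lymphoid spots the highest 5% of all spots by their scores, and a spot within 0.1 of a limit was called near it. The cortex markers were Slc34a1, Slc5a2, Slc5a12, Lrp2, Slc22a6, Slc22a8, Slc13a3, Miox, Gatm, Pck1, Ass1 and Slc4a4, and the medulla markers Umod, Slc12a1, Aqp2, Aqp3, Aqp4, Fxyd4, Akr1b3, Slc14a2, Apela, Cryab, Hsd11b2 and Cldn10. Glomerular markers included Nphs1, Podxl, Synpo, Ptpro, Clic5, Cdkn1c, Tcf21, Ehd3 and Wt1, and lymphoid markers included Cd3e, Cd3d, Cd3g, Cd2, Trbc2, Ms4a1, Cd79a, Cd79b, Ltb, Cd37 and Ighd. Counts were summed per section and class and tested with edgeR with the section as a block, leaving out the genes used to choose the spots. Spots are regions that mix cells. Some genes that the rules for markers and named genes take in are not reported here.

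The comparisons, gene lists, markers, thresholds and alternatives were chosen before the data were examined, except where the text says otherwise. Genes were named by a fixed rule: the 8 largest fold changes in each direction that passed, with a mean of at least 5 CPM in one group and with groups that did not overlap (bulk, where chance gives 10% for 3 against 3) or the same sign in all 4 sections (spatial). This ranking skipped unnamed gene models, variable segments of immunoglobulin and receptor genes, and spot markers. In addition 18 genes were always named in bulk, up to 4 members of a described list by smallest adjusted p, and up to 20 genes from the Moran's I tables. A fold change against a group at 0 is given as a bound from a floor of 3 counts over the group, and ratios with 1 to 3 counts with an exact 95% interval. Coordinates are GRCm38, matched by symbol to a RefSeq table of the same build.

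Libraries with the same number at 10 and 20 weeks had deviations from their age means that correlated at 0.130 to 0.218 across genes, and those of different numbers at -0.182 to 0.0239. All same-number values were above 0.1, which meets the fixed rule for pairing, but the labels do not state a pairing. Libraries of different numbers reached 0.320 and 0.476 in the pairs of ages with 30 weeks. Values of this size thus also occur without a shared number and do not establish a pairing. The main fit of all 9 libraries had no block and so ignores any such pairing. Genes passing for 20 against 10 weeks are therefore also given with the number as a block. Between 10 and 30 weeks libraries of the same number gave -0.279 to 0.0919 and those of different numbers -0.0716 to 0.320. Between 20 and 30 weeks they gave -0.428 to 0.187 and -0.345 to 0.476. By the same rule the numbers do not pair the 30-week libraries with either earlier age. A block over all 9 libraries nevertheless applies the numbers to the 30-week libraries as well.

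The tests were checked on simulated counts with 200 genes changed 1.5-, 2- or 4-fold. The changed genes were drawn only from genes above a minimum mean CPM, so the recovered shares do not cover tested genes at lower levels. The simulated counts varied independently from gene to gene. Deviations that many genes of a library share were left out, so the recovered shares may be too high for the real samples. Of genes changed 2-fold, 62.7% were recovered for 20 against 10 weeks, 61.2% for 30 against 10 weeks and 65.7% for 30 against 20 weeks, with 13, 2 and 10 false calls. The recovered share at 2-fold was 10.4% for the difference between intervals, 74.6% for any difference among ages, and 92.5%, 73.1% and 70.1% for the zones, glomerular spots and lymphoid spots. Alternatives included DESeq2 1.42.0, other filters, thresholds and spot limits, a block for the replicate number and leaving out each library or section. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.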

Results

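Kidney RNA was measured in female NZB/W F1 mice, the hybrid of the New Zealand Black and New Zealand White strains that develops a lupus nephritis as it ages. Poly(A) RNA of the whole kidney was sequenced in 3 libraries for each age (10, 20 and 30 weeks). In addition, 4 frozen sections of 30-week kidney were measured on Visium slides, an array of barcoded spots that each record the RNA of a small tissue region. The labels number the libraries and sections without naming the animals, so p-values measure only the spread between these samples, which may be technical in part. Reads assigned to genes numbered 33679213, 39344693 and 28776366 in the 10-week libraries. They numbered 35835365, 31527354 and 30527210 at 20 weeks, and 30913795, 38041788 and 30648820 at 30 weeks. The sections held 14453112, 15501138, 6964511 and 6157933 unique molecules (UMIs), so sections 3 and 4 were the shallower pair. After filtering, 2935, 2739, 2619 and 2425 spots remained, with medians of 3844, 4027, 1995 and 1860 UMIs per spot. On the first principal component of the bulk libraries, which held 67.2% of the variance, the 30-week libraries lay between 55.2 and 81.4 and all others between -45.2 and -23.5.

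The first question was how kidney RNA changed over the whole period, from 10 to 30 weeks. Most tested genes of the complement, matrix, macrophage and tubular injury lists rose, and many but not all markers of the first proximal segments and of the distal tubule fell. None of these lists passed with an estimated correlation (adjusted p = 0.0683 for the matrix and injury lists, 0.108 for macrophage and 0.138 for complement genes, 0.341 for the first proximal segments and 0.242 for the distal tubule). C3, the central complement component (chromosome 17, 57203967 to 57228136), went from 49.9 ± 4.65 CPM (counts scaled to library size; SD, n = 3) to 1205 ± 417, a log2 fold change of 4.59 ± 0.28 (SE; adjusted p = 7.69e-06). Spp1, which encodes osteopontin (chromosome 5, 104435111 to 104441053), went from 1544 ± 390 to 21341 ± 4167 CPM (SD, n = 3). Lcn2, the iron-binding injury marker lipocalin 2 (chromosome 2, 32384637 to 32387739), rose by 5.87 ± 0.47 on the log2 scale (SE; adjusted p = 1.67e-05), and Havcr1, which encodes the injury marker KIM-1 (chromosome 11, 46739822 to 46779578), by 3.36 ± 0.27 (adjusted p = 1.56e-05). In the other direction, Slc34a1, the main phosphate cotransporter of the proximal tubule (chromosome 13, 55399622 to 55414695), fell from 3728 ± 978 to 1685 ± 374 CPM (SD, n = 3), a log2 change of -1.15 ± 0.23 (SE; adjusted p = 0.00373).

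The other preselected genes of inflammation and repair rose as well. These were Vcam1, a leukocyte adhesion molecule (3.49 ± 0.22, log2 ± SE), Col1a1, a chain of type I collagen (4.17 ± 0.33), Fn1, fibronectin (3.28 ± 0.37), C1qa, a chain of complement C1q (2.77 ± 0.32), Cd74, the class II invariant chain (2.15 ± 0.28), Cxcl13, a B cell chemoattractant (3.83 ± 0.69), Jchain, the joining chain of secreted immunoglobulin (3.61 ± 0.56), and Isg15, an interferon-induced ubiquitin-like protein (2.01 ± 0.49). Their adjusted p-values ran from 7.82e-06 for Vcam1 to 0.00997 for Isg15. Slc5a2, the glucose transporter SGLT2, fell by 1.69 (SE 0.43, adjusted p = 0.0122), and Slc12a1, the sodium-potassium-chloride cotransporter of the thick limb, by 0.93 (SE 0.23, adjusted p = 0.0108). The Slc5a2 call was lost without 10-week replicate 2 (-1.28) or 30-week replicate 1 (-1.43). Nphs1, which encodes the podocyte protein nephrin (-0.20, adjusted p = 0.443), and Umod, uromodulin of the thick limb (-0.35, adjusted p = 0.276), did not pass the test. The largest rises among genes of at least 5 CPM were in Mmp7, a matrix metalloproteinase (7.40 ± 0.99), Il1f6, an interleukin-1 family cytokine (7.11 ± 0.59), Cxcl17 (7.08 ± 0.58), Saa1, an acute-phase apolipoprotein (6.83 ± 0.74), Arhgap36 (6.70 ± 0.64), Il1rn, the interleukin-1 receptor antagonist (6.21 ± 0.38), Sult4a1 (6.06 ± 0.49) and Timp1, a metalloproteinase inhibitor (6.06 ± 0.39). The largest falls were in the potassium channel gene Kcns1 (-4.79 ± 0.35), Cyp2d12 (-4.65 ± 0.49), Pvalb, the calcium-binding parvalbumin of the distal convoluted tubule (-4.60 ± 0.76), Kcnt1 (-3.84 ± 0.59), Serpina6, corticosteroid-binding globulin (-3.73 ± 0.28), Prss35 (-3.72 ± 0.61), Hpd, an enzyme of tyrosine breakdown (-3.35 ± 0.43), and Dnase1, a secreted nuclease (-3.15 ± 0.33).

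**Figure D1:**
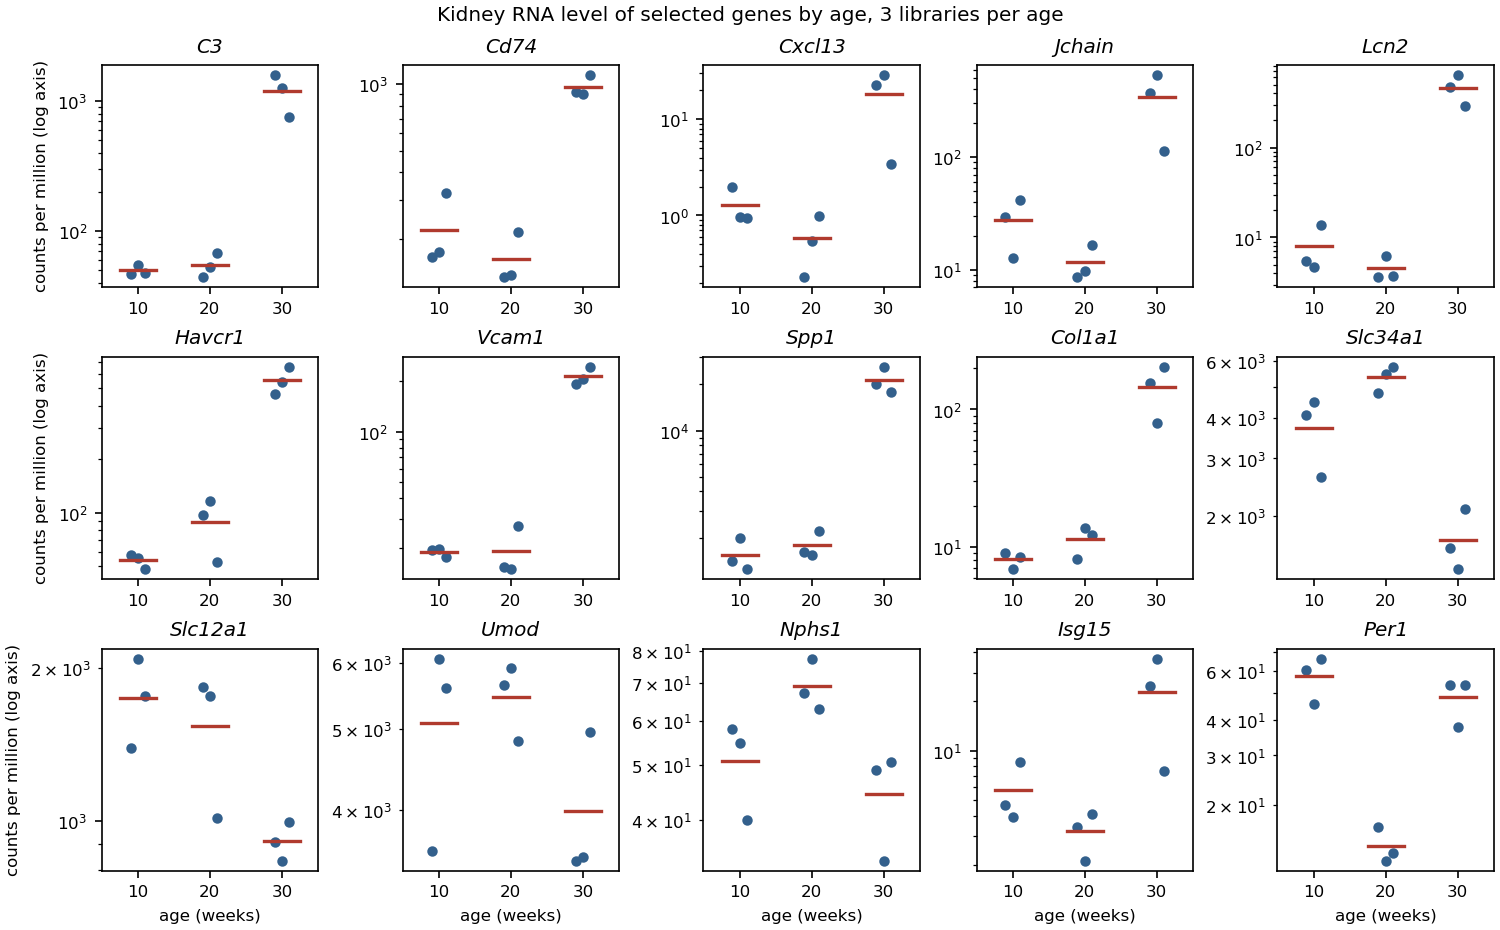
Level of selected genes in CPM (log axis) in each whole-kidney library at 10, 20 and 30 weeks; points are the 3 libraries of an age and lines their means. C3 averages 49.9, 55.3 and 1205 CPM and Slc34a1 3728, 5332 and 1685 CPM, so that the 30-week libraries stand apart from both earlier ages, and Per1 is lowest at 20 weeks (14.3 CPM).

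Most immune lists rose from 10 to 30 weeks. In the macrophage and monocyte list 20 of 21 tested genes rose and 1 did not pass (20 adjusted over the list alone; camera adjusted p = 3.18e-26, adjusted p = 0.108 with an estimated correlation). Members with small p-values were Itgam (4.46 ± 0.32), an integrin of myeloid cells, and Adgre1 (2.41 ± 0.19), which encodes F4/80. All 14 complement genes rose (14 adjusted over the list alone; camera adjusted p = 1.02e-17, adjusted p = 0.138 with an estimated correlation). C4b was at 3.41 ± 0.27. Of the inflammatory chemokines and cytokines 18 of 19 rose (18 adjusted over the list alone; camera adjusted p = 2.97e-15, adjusted p = 0.172 with an estimated correlation). Il34, a ligand of the macrophage growth factor receptor, rose by 2.45 ± 0.17. The antigen presentation lists rose in 10 of 10 class II genes (10 adjusted over the list alone; camera adjusted p = 4.67e-10, adjusted p = 0.242 with an estimated correlation). Class I genes rose in 11 of 12 (12 adjusted over the list alone; camera adjusted p = 8.09e-07, adjusted p = 0.319 with an estimated correlation). Interferon genes followed, with 16 of 17 interferon-gamma-induced genes up (17 adjusted over the list alone; camera adjusted p = 7.44e-12, adjusted p = 0.176 with an estimated correlation). Of 20 type I interferon genes 15 rose and 5 did not pass (16 adjusted over the list alone; camera adjusted p = 9.05e-07, adjusted p = 0.400 with an estimated correlation). Examples were Gbp5 (2.05 ± 0.18), a guanylate-binding protein, and Oasl2 (2.38 ± 0.36).

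Lymphocyte markers rose too. Of 13 T cell markers 12 rose (12 up and 1 down adjusted over the list alone; camera adjusted p = 4.23e-05, adjusted p = 0.376 with an estimated correlation). Cd8b1, a CD8 chain, was at 3.43 ± 0.48 and the kinase gene Lck at 2.39 ± 0.38. Of 11 B cell markers 8 rose and 3 did not pass (9 adjusted over the list alone; camera adjusted p = 0.00858, adjusted p = 0.538 with an estimated correlation). Ms4a1, which encodes CD20, was at 3.04 ± 0.64. Plasma cell genes rose in 5 of 6 tested (5 adjusted over the list alone; camera adjusted p = 0.000589, adjusted p = 0.315 with an estimated correlation). Genes of lymphoid aggregates rose in 5 of 10 (7 adjusted over the list alone; camera adjusted p = 0.00644, adjusted p = 0.412 with an estimated correlation). Ltb, lymphotoxin beta, was at 2.93 ± 0.49. The neutrophil list (3 of 6 rose, 5 adjusted over the list alone; camera adjusted p = 0.0746, adjusted p = 0.354 with an estimated correlation) and the dendritic cell list (3 of 12 rose, 4 adjusted over the list alone; camera adjusted p = 0.0765, adjusted p = 0.539 with an estimated correlation) did not pass. Without 10-week replicate 3 both passed (0.0304 and 0.0195), and the dendritic cell list also without 20-week replicate 3 (0.0471) or 30-week replicate 1 (0.04999). Among proliferation genes 16 of 18 rose (16 adjusted over the list alone; camera adjusted p = 3.56e-16, adjusted p = 0.0987 with an estimated correlation). Top2a was at 3.68 ± 0.28 and Mki67 at 3.21 ± 0.30.

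The extracellular matrix and tubular injury lists had the smallest p-values of this comparison. In the extracellular matrix list 21 of 23 genes rose and 2 did not pass (22 adjusted over the list alone; camera adjusted p = 5.63e-37, adjusted p = 0.0683 with an estimated correlation). Col6a1, a chain of collagen VI, rose by 3.15 ± 0.16 and Loxl1, which cross-links elastin, by 2.64 ± 0.16. In the tubular injury list 19 of 20 rose and 1 fell (19 and 1 adjusted over the list alone; camera adjusted p = 1.54e-27, adjusted p = 0.0683 with an estimated correlation). Its member with the smallest p-value was Dcdc2a, at 2.53 ± 0.13. Acute-phase genes rose in 12 of 13 (13 adjusted over the list alone; camera adjusted p = 1.50e-17, adjusted p = 0.147 with an estimated correlation). Fga, a fibrinogen chain, was at 2.98 ± 0.21. NF-kB targets rose in 10 of 13 and fell in 2 (10 and 2 adjusted over the list alone; camera adjusted p = 5.05e-14, adjusted p = 0.0806 with an estimated correlation). Icam1 was at 2.17 ± 0.12.

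Tubule genes fell in several segments of the nephron, the last proximal segment not among them. Of 15 markers of the first proximal segments 9 fell and 6 did not pass (9 adjusted over the list alone; camera adjusted p = 4.50e-05, adjusted p = 0.341 with an estimated correlation). Slc13a3, a dicarboxylate transporter, was at -1.33 ± 0.15. Thick limb markers fell in 7 of 10 and rose in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.000633, adjusted p = 0.264 with an estimated correlation). Egf, the precursor of epidermal growth factor, was at -2.59 ± 0.28. Distal tubule markers fell in 6 of 9 (6 down and 1 up adjusted over the list alone; camera adjusted p = 0.000847, adjusted p = 0.242 with an estimated correlation). The magnesium channel gene Trpm6 was at -2.48 ± 0.20, while Trpv5, a calcium channel gene of the same segment, rose by 1.81 ± 0.16. Principal cell markers fell in 6 of 10 (6 adjusted over the list alone; camera adjusted p = 0.000424, adjusted p = 0.0987 with an estimated correlation). The vasopressin receptor gene Avpr2 was at -1.33 ± 0.13. Among genes of gluconeogenesis and amino acid handling 12 of 16 fell (12 adjusted over the list alone; camera adjusted p = 1.05e-05, adjusted p = 0.315 with an estimated correlation). Of 26 oxidative phosphorylation genes 14 fell and 12 did not pass (19 adjusted over the list alone; camera adjusted p = 9.40e-06, adjusted p = 0.478 with an estimated correlation). The list of the last proximal segment did not shift as a whole (2 up, 1 down, 8 not passing; 2 up and 1 down adjusted over the list alone; camera adjusted p = 0.448, adjusted p = 0.747 with an estimated correlation). The podocyte list (3 up, 1 down, 10 not passing; camera adjusted p = 0.770), the endothelial list (1 up, 5 down, 6 not passing; camera adjusted p = 0.206) and the fatty acid oxidation list (3 up, 3 down, 13 not passing; camera adjusted p = 0.773) did not pass either. The endothelial receptor gene Kdr fell by 0.98 (SE 0.17, adjusted p = 0.0013).

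In this comparison 5047 of 15706 genes passed the edgeR test, 2765 up and 2282 down, of which 1569 rose and 845 fell at least 2-fold. With an estimated correlation 0 of the 117 list tests over the 3 pairs of ages passed (camera; 24 at an unadjusted p under 0.05). With the preset correlation 68 passed, and 63 by fry, which asks only whether the genes of a list move one way. Of 10 splits of the 10- and 30-week libraries, the real one included, 3 called at least as many lists as the real 28. These counts were adjusted within this comparison, and the highest other was 30. The number of lists passing with the preset correlation therefore cannot be told from an arbitrary grouping here either. The authors' deposited table for the same pair of ages listed 17342 genes with 3046 up and 2594 down at an adjusted p under 0.05, and 4997 of the 5047 edgeR calls (99.0%) were called there in the same direction.

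**Figure D2:**
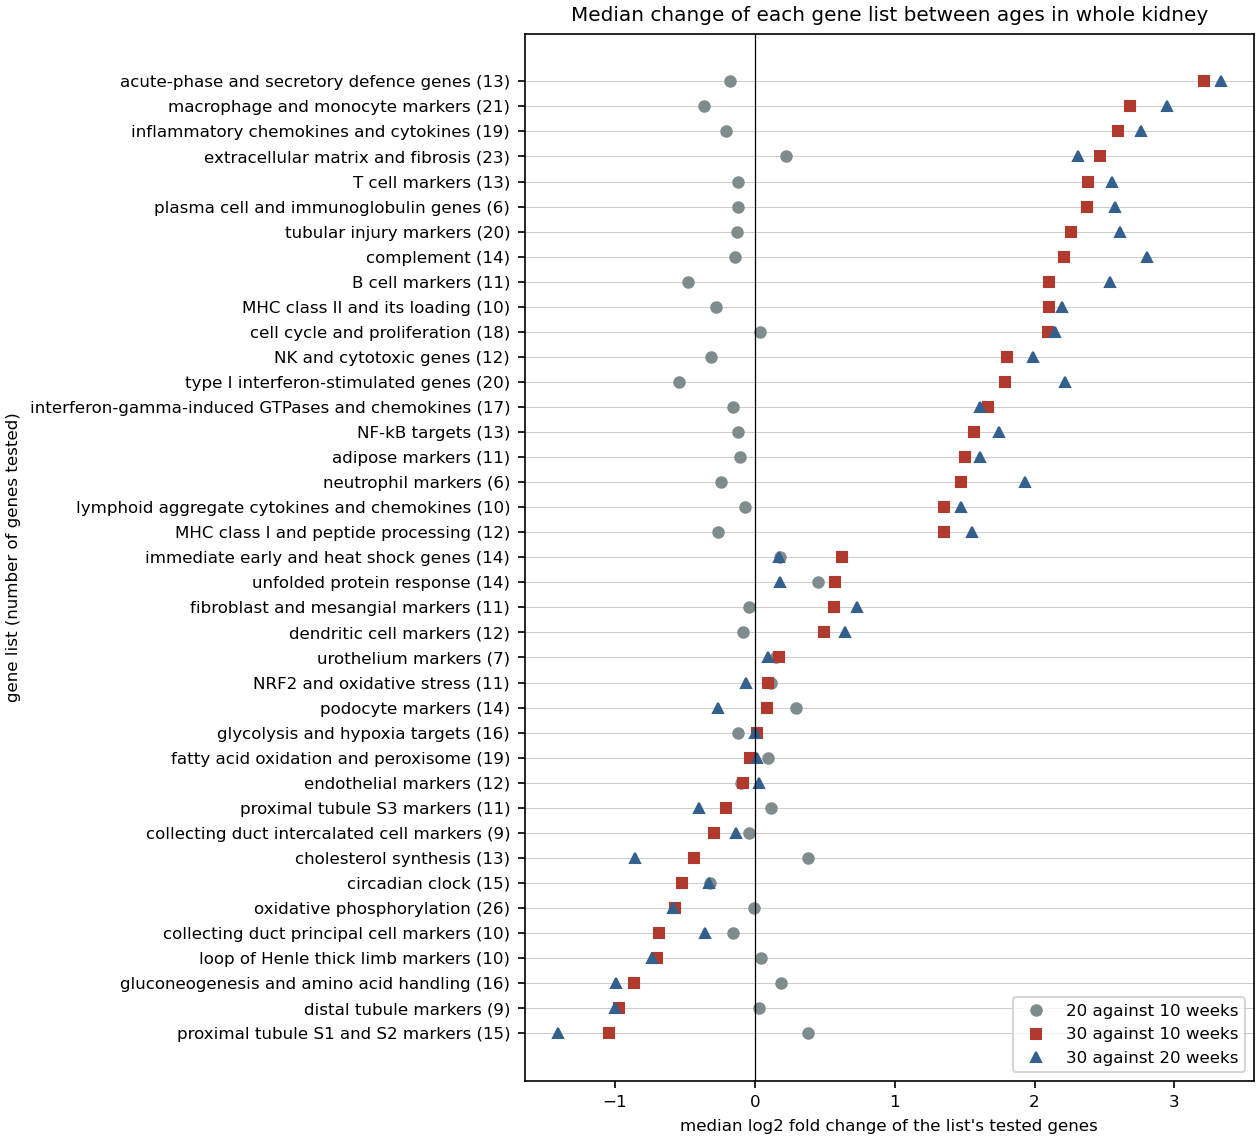
Median log2 fold change of the tested genes of each list between ages in whole kidney; circles compare 20 with 10 weeks, squares 30 with 10 weeks and triangles 30 with 20 weeks. The matrix list has a median of 2.47 for 30 against 10 weeks and 0.22 for 20 against 10 weeks, and the list of the first proximal segments has -1.04 and 0.38.

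The later interval, from 20 to 30 weeks, was compared next. C3 rose by 4.45 ± 0.28 (log2 ± SE; adjusted p = 6.81e-06), Spp1 by 3.58 ± 0.27 (adjusted p = 1.16e-05) and Lcn2 by 6.68 ± 0.50 (adjusted p = 1.12e-05), while Slc34a1 fell by 1.66 (SE 0.24, adjusted p = 0.0004). The large rises included Cxcl17 (7.59 ± 0.62), Arhgap36 (7.22 ± 0.68), Il1f6 (7.10 ± 0.59), Vgf, a neuropeptide precursor (6.89 ± 0.84), and Timp1 (6.10 ± 0.40). Saa1 had 0 counts in the 20-week libraries and 6.01 ± 3.18 CPM at 30 weeks (SD, n = 3), which is at least 196-fold higher against a floor of 3 counts over the group. Mmp7 had 2 counts over the 20-week libraries and 779 over the 30-week libraries, a log2 ratio of 8.58 with a 95% exact counting interval of 6.72 to 11.63. The largest falls were in Serpina6 (-4.28 ± 0.28), Pvalb (-4.26 ± 0.75), Kcns1 (-4.19 ± 0.35), Kcnt1 (-3.43 ± 0.59), Clec2h (-3.36 ± 0.24), Pdzrn4 (-3.22 ± 0.35), Galnt9 (-3.17 ± 0.52) and Hpd (-3.17 ± 0.43).

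Type I interferon genes rose in 18 of 20 between 20 and 30 weeks (18 adjusted over the list alone; camera adjusted p = 2.47e-09, adjusted p = 0.319 with an estimated correlation). Markers of the first proximal segments fell in 12 of 15 (14 adjusted over the list alone; camera adjusted p = 2.34e-08, adjusted p = 0.242 with an estimated correlation). Cholesterol synthesis genes fell in 11 of 13 (12 down and 1 up adjusted over the list alone; camera adjusted p = 0.000107, adjusted p = 0.319 with an estimated correlation). Insig1, a regulator of sterol sensing, was at -2.03 ± 0.30. Nphs1 fell by 0.64 in this interval (SE 0.18, adjusted p = 0.0199), a call lost without 20-week replicate 2 (-0.55) or 30-week replicate 2 (-0.46). The test passed 5159 genes, 2874 up and 2285 down. Of these, 2371 were up and 1672 down in the comparison of 30 with 10 weeks as well, and 0 were called in opposite directions. Both comparisons share the 30-week libraries, so part of the overlap may come from them. In a check chosen after seeing the data, all 9 libraries were simulated anew without any change between ages. The same comparisons then shared 0.1 calls on average and at most 2 in 20 simulations. With nothing changed few genes are called at all, so this cannot tell how much of the overlap comes from the shared libraries. Independent lists of these sizes would share 506 going up and 332 going down. Among genes that rose at least 2-fold from 10 to 30 weeks, the median share of the change already present at 20 weeks was -6.71%, and among those that fell it was 13.7%.

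From 10 to 20 weeks a single gene passed the main test, which has no block for the replicate number. Per1, a core repressor of the circadian clock (chromosome 11, 69095108 to 69109965), fell from 57.5 ± 10.6 to 14.3 ± 2.12 CPM (SD, n = 3), a log2 change of -2.01 ± 0.19 (SE; adjusted p = 0.00596), and it returned to 48.4 ± 8.97 CPM at 30 weeks (1.76 ± 0.19 over 20 weeks, adjusted p = 6.91e-05). The immediate early gene Egr1 differed by 2.77 ± 0.40 without passing (adjusted p = 0.123), and Fos by 2.65 ± 0.59 (adjusted p = 0.315). Libraries with the same number deviated together at these ages, so the fixed rule for pairing calls for the number as a block, although a pairing is not established. With that block over all 9 libraries, which also applies the numbers to the 30-week libraries, 4 genes passed. These were Egr1 (2.69 ± 0.25, adjusted p = 0.0146), Per1 (adjusted p = 0.00191), the kinase gene Pim3 (-1.23 ± 0.13, adjusted p = 0.0251) and Tsc22d3, which encodes the glucocorticoid-induced protein GILZ (-1.25 ± 0.14, adjusted p = 0.0344). A fit with the block on the libraries of these 2 ages alone, chosen after seeing the data, passed 7 genes, namely Per1, Egr1, Tsc22d3, Igf2 (-1.26 ± 0.12), Ly6f (1.88 ± 0.18), Slc22a26 (1.64 ± 0.13) and Usp2 (-1.17 ± 0.12).

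Several lists passed camera with the preset correlation over the same weeks, with few members passing on their own. Of 10 splits of these libraries, the real one included, 4 called at least as many lists as the real 13, adjusted within this comparison. The highest other called 18, so these list results cannot be told from an arbitrary grouping. Of 14 genes of the unfolded protein response 0 passed over all genes, and 9 rose and 2 fell adjusted over the list alone (median 0.45, camera adjusted p = 2.51e-07, adjusted p = 0.108 with an estimated correlation). Pdia4, a disulfide isomerase, was at 0.60 ± 0.13 (adjusted p = 0.305). Immediate early and heat shock genes gave 0 of 14 over all genes and 6 up and 1 down adjusted over the list alone (camera adjusted p = 7.53e-07, adjusted p = 0.188 with an estimated correlation). Circadian clock genes gave 1 of 15 over all genes, Per1, and 2 up and 5 down adjusted over the list alone (median -0.32, camera adjusted p = 0.000556, adjusted p = 0.242 with an estimated correlation). Unlike Per1, the list stayed lower at 30 than at 10 weeks, with 6 down and 1 up over all genes (median -0.52, camera adjusted p = 0.0370, adjusted p = 0.400 with an estimated correlation). Neither over all genes nor adjusted over the list alone did any member pass in the podocyte list (median 0.30, camera adjusted p = 1.60e-07, adjusted p = 0.147 with an estimated correlation), the cholesterol synthesis list (0.38, camera adjusted p = 8.09e-07, adjusted p = 0.242 with an estimated correlation), the list of the first proximal segments (0.38, camera adjusted p = 6.49e-06, adjusted p = 0.315 with an estimated correlation) or the type I interferon list (-0.54, camera adjusted p = 0.000223, adjusted p = 0.514 with an estimated correlation). The macrophage list had a median of -0.36 with no member passing either way (camera adjusted p = 0.000379, adjusted p = 0.473 with an estimated correlation), and that call was lost without 20-week replicate 2 (0.0793).

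Without the block Per1 was the 1 call of edgeR among 15706 genes, with 0 up, 1107 at an unadjusted p under 0.05 and 73 passing in DESeq2. The count was 0 without 10-week replicate 1, where Per1 was at -1.97. It was 2, 2 and 6 without 20-week replicates 1, 2 and 3, and 9 without 30-week replicate 3. The test over all 3 ages passed 5000 genes, 3287 without 30-week replicate 1. A test of whether the change per interval itself differed passed 2055 genes, 1342 with the larger value in the later interval and 713 with the larger value in the earlier one; C3 (difference 4.30, adjusted p = 0.00108) and Slc34a1 (-2.18, adjusted p = 0.0063) were among them. That count was 786 without 20-week replicate 1 and 1168 without 20-week replicate 2. Of the calls for 20 and for 30 weeks against 10 weeks 0 were shared in edgeR. Independent lists of these sizes would share 0.145 going down and 0 going up. DESeq2's calls shared 18 going up and 17 going down, against 5.47 and 7.91 for independent lists. Part of the excess may come from the shared 10-week libraries. With all libraries simulated anew and unchanged, 0.05 calls were shared on average in edgeR and 0.65 in all (at most 3) in DESeq2. With nothing changed few genes are called at all, so these simulations cannot tell how large that part is.

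The sections of 30-week kidney were compared by region. Spots were assigned to a medulla or a cortex zone by a score over preselected tubule markers, which were then left out of the tests. Other genes of the cells that the markers stand for were still tested. In all 3 spatial comparisons such genes differ in part through the choice of spots, and their p-values do not test that choice. Cortex zones held 1032, 941, 830 and 734 spots and medulla zones 820, 741, 710 and 594, and 378 to 403 spots per section lay near a limit of the score. Markers of the urothelium, the lining of the renal pelvis, were higher in the medulla than in the cortex zone in 5 of 5 tested (5 adjusted over the list alone; camera adjusted p = 1.88e-07, adjusted p = 0.186 with an estimated correlation). Upk3a, a uroplakin (chromosome 15, 85017141 to 85022560), was at 119 ± 56.4 CPM there and 2.29 ± 0.906 in the cortex zone (SD, n = 4), a log2 difference of 5.63 ± 0.15 (SE; adjusted p = 2.84e-45). Other genes higher in the medulla zone were Upk1b (5.53 ± 0.39), Gsdmc2 (5.36 ± 0.34), Lypd2 (5.12 ± 0.18) and the urea transporter gene Slc14a1 (5.03 ± 0.31). For Krt5, Npvf and Nptx1 the cortex zones held 3, 2 and 2 counts in all, and the log2 ratios of summed counts were 6.02, 5.68 and 5.49 with 95% exact counting intervals that start at 4.43, 3.76 and 3.57. Among the genes higher in the cortex zone by large factors were Mogat2 (-4.26 ± 0.29), Fabp1, a fatty acid carrier (-3.98 ± 0.32), Bhmt, which remethylates homocysteine (-3.97 ± 0.18), Dpys (-3.96 ± 0.36), Nat8f3 (-3.85 ± 0.32), Cyp2e1 (-3.81 ± 0.14) and Ces1e (-3.75 ± 0.13). Nepn had 2 counts in the medulla zones against 102 in the cortex zones (log2 ratio -4.88, interval -7.94 to -2.99).

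**Figure D3:**
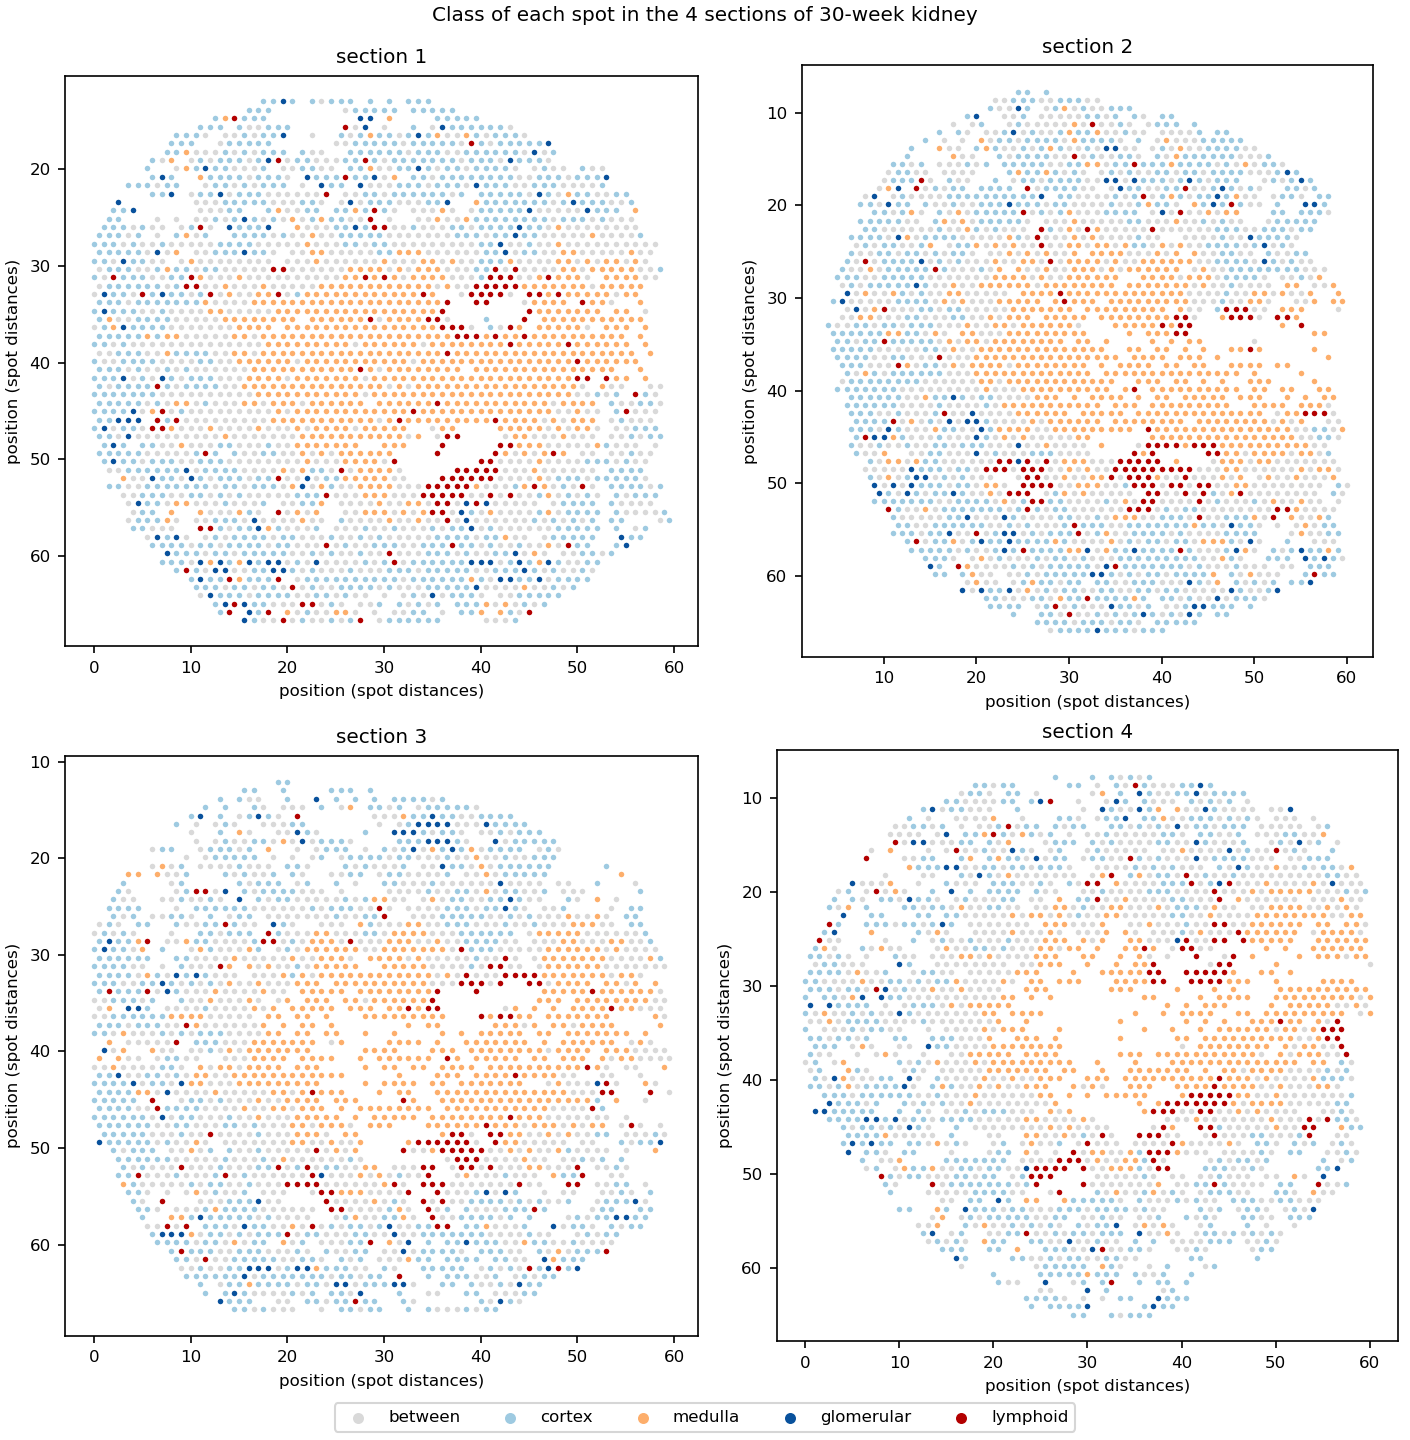
Position of each spot in the 4 sections of 30-week kidney, in spot distances, coloured by its class. Medulla zones hold 820, 741, 710 and 594 spots, glomerular spots number 103, 94, 83 and 73, and lymphoid spots 147, 137, 131 and 121.

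All 13 tested genes of gluconeogenesis and amino acid handling were lower in the medulla zone (13 adjusted over the list alone; camera adjusted p = 2.01e-20, adjusted p = 0.124 with an estimated correlation). Pck1, Ass1 and Gatm of this list were cortex markers, and Umod, Slc12a1 and Cldn10 of the thick limb list were medulla markers. Both lists therefore differ in part through the choice of spots. Glycolysis and hypoxia genes leaned the other way, with 9 of 14 higher in the medulla zone and 4 lower (9 and 4 adjusted over the list alone; camera adjusted p = 0.00848, adjusted p = 0.182 with an estimated correlation). Oxidative phosphorylation genes did not pass as a list (10 of 26 higher, 4 lower; camera adjusted p = 0.181). Lower in the medulla zone were 12 of 18 fatty acid oxidation genes, with 2 higher (13 and 2 adjusted over the list alone; camera adjusted p = 1.19e-08, adjusted p = 0.104 with an estimated correlation). Higher there were 6 of 7 thick limb markers (6 up and 1 down adjusted over the list alone; camera adjusted p = 2.27e-07, adjusted p = 0.209 with an estimated correlation). Plasma cell and immunoglobulin genes were higher in 11 of 14 (11 up and 1 down adjusted over the list alone; camera adjusted p = 2.60e-07, adjusted p = 0.287 with an estimated correlation). Igkc, the kappa light chain constant gene, was at 1.35 ± 0.09. Adipose markers were higher in 4 of 5 (4 adjusted over the list alone; camera adjusted p = 0.0152, adjusted p = 0.209 with an estimated correlation), with Fabp4 at 1.77 ± 0.07. Red blood cell genes were higher in 3 of 6 and lower in 1 (3 and 2 adjusted over the list alone; camera adjusted p = 0.00662, adjusted p = 0.287 with an estimated correlation), with Hbb-bs at 1.57 ± 0.06. Tubular injury markers were higher in 9 of 17 and lower in 4 (9 and 5 adjusted over the list alone; camera adjusted p = 0.00544, adjusted p = 0.226 with an estimated correlation). Havcr1 was at 2.16 ± 0.09 and Lcn2 at 1.93 ± 0.08. Complement genes went both ways (5 up, 4 down, not passing as a list), with C3 at -1.12 ± 0.08 and C1qc at 0.90 ± 0.07. The test passed 5235 of 11710 genes, 2792 higher and 2443 lower in the medulla zone, with the same sign in all 4 sections for 4725. DESeq2 passed 3231. Depth differed between the zones in every section; in section 2 the median spot held 5359 UMIs in the cortex zone and 2061 in the medulla zone.

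Glomerular spots, the 10% of cortex zone spots with the highest score for podocyte and glomerular markers, were compared with the other cortex zone spots. They numbered 103, 94, 83 and 73, and 41 to 64 spots per section lay near the limit. Cortex zone spots were chosen mainly by proximal tubule markers, so spots with strong glomerular but weak proximal signal could be left out. Plat, tissue plasminogen activator (chromosome 8, 22757722 to 22782848), was at 97.2 ± 25.6 CPM in glomerular spots and 25.5 ± 8.99 in the others (SD, n = 4), a log2 difference of 2.12 ± 0.17 (SE; adjusted p = 3.80e-16). Other genes higher there were Myom2 (2.74 ± 0.39), Nell2 (2.64 ± 0.46), Clic3 (2.53 ± 0.28), Fgfbp1 (2.38 ± 0.26), Rab3b (2.27 ± 0.30), Wipf3 (2.23 ± 0.42) and the natriuretic peptide receptor gene Npr3 (2.05 ± 0.38). Lower were the immunoglobulin lambda gene Iglc1 (-1.83 ± 0.22), Ccl28 (-1.32 ± 0.22), Zfp946 (-1.54 ± 0.51), Gfra1 (-1.26 ± 0.38), Klhl7 (-1.22 ± 0.39) and Slc7a12 (-1.21 ± 0.41). Some calls were lost when single sections were left out. Zfp946 lost it without section 1 (-1.04), 3 (-1.56) or 4 (-1.66) and Gfra1 without section 1 (-1.29), 2 (-1.34) or 4 (-1.08). Klhl7 lost it without section 2 (-1.08), 3 (-0.96) or 4 (-1.25) and Slc7a12 without section 1 (-1.55), 2 (-0.93) or 3 (-1.02). Iglc1 lost it without section 1 (-0.64). For Magix and Slc23a3 the glomerular spots held 3 counts each (log2 ratios of summed counts -2.57 and -2.31, the second with an interval of -4.61 to -0.74). Slc23a3 did not pass without section 1 (-2.29) or 2 (-1.67).

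Matrix genes were higher in 11 of 19 in glomerular spots and lower in 0 (14 adjusted over the list alone; camera adjusted p = 5.54e-17, adjusted p = 0.124 with an estimated correlation). Ccn2, connective tissue growth factor, was at 1.27 ± 0.08 and Col4a1, a chain of basement membrane collagen, at 0.57 ± 0.08. Macrophage markers were higher in 10 of 18 (13 up and 1 down adjusted over the list alone; camera adjusted p = 4.14e-12, adjusted p = 0.148 with an estimated correlation), such as Lyz2 (0.68 ± 0.07). In the tubular injury list 5 of 15 genes were higher and 10 did not pass (7 up and 2 down adjusted over the list alone; camera adjusted p = 1.88e-07, adjusted p = 0.104 with an estimated correlation), with Vim at 1.37 ± 0.10. Spots mix cells and these were chosen by glomerular markers, so the list does not show that tubules were more injured there. Distal tubule markers were higher in 3 of 8 (3 adjusted over the list alone; camera adjusted p = 0.0155, adjusted p = 0.363 with an estimated correlation), and the list did not pass without section 1 (0.0864) or section 3 (0.259). Complement genes were higher in 7 of 13 (9 adjusted over the list alone; camera adjusted p = 4.21e-08, adjusted p = 0.226 with an estimated correlation), with C3 at 0.63 ± 0.09. Endothelial markers were higher in 4 of 11 (6 adjusted over the list alone; camera adjusted p = 5.24e-06, adjusted p = 0.104 with an estimated correlation). Fibroblast and mesangial markers were higher in 4 of 11 (5 adjusted over the list alone; camera adjusted p = 0.000132, adjusted p = 0.226 with an estimated correlation), among them Ren1, renin of the juxtaglomerular cells (1.87 ± 0.16). All 7 tested markers of the last proximal segment were lower (7 adjusted over the list alone; camera adjusted p = 4.08e-22, adjusted p = 0.107 with an estimated correlation). So were 15 of 26 oxidative phosphorylation genes (21 adjusted over the list alone; camera adjusted p = 1.41e-14, adjusted p = 0.104 with an estimated correlation). Type I interferon genes were higher in 1 of 17, Ifi27l2a (0.43 ± 0.09, though at -0.15 in section 4 alone), and 2 adjusted over the list alone (camera adjusted p = 0.00811, adjusted p = 0.269 with an estimated correlation).

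The comparison passed 856 of 9541 genes, 421 higher and 435 lower (49.2% higher), and 354 in DESeq2 (30.8% higher). It passed 390 without section 2, 563 without section 1 and 445 with no block for the section (63.1% higher), and without the filter on low counts 33.9% of the calls were higher.

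Lymphoid spots, the 5% of all spots with the highest score for B and T cell markers, were compared with all others. Other genes of B and T cells are thus higher there in part through the choice of spots. They numbered 147, 137, 131 and 121, 41 to 64 spots per section lay near the limit, and 24.8 to 31.3% of them lay in the medulla zone and 9.92 to 17.7% in the cortex zone. Of the other spots 24.2 to 27.8% lay in the medulla zone and 31.3 to 36.1% in the cortex zone, so that a smaller share of lymphoid spots than of other spots lay in the cortex zone. Cxcl13 was at a log2 difference of 4.19 ± 0.10 (SE; adjusted p = 3.06e-48). Reg3g, a secreted antibacterial lectin (chromosome 6, 78466269 to 78468874), reached 112 ± 82.0 CPM there against 1.42 ± 0.693 elsewhere (SD, n = 4), a difference of 6.05 ± 0.26 (SE; adjusted p = 2.32e-32). Also higher were the keratin gene Krt17 (5.26 ± 0.47), Abcc8 (4.97 ± 0.77), Mmp7 (4.96 ± 0.45), Il9r (4.92 ± 0.69), Glycam1, a ligand of L-selectin on high endothelial venules (4.81 ± 0.39), Ly6d (4.76 ± 0.14) and the B cell gene Fcrla (4.66 ± 0.36). The genes lower by the largest factors were near the detection limit. Alkal2 had 0 counts in lymphoid spots and 5.35 ± 1.20 CPM elsewhere (SD, n = 4), at least 3.24-fold lower against a floor of 3 counts over the group. Olfm3, Frmd8os, Fam124a, Etnk2, Bglap3 and Zscan22 had 1 or 2 counts in all lymphoid spots. The log2 ratios of summed counts lay between -3.68 for Olfm3 (interval -8.99 to -1.19) and -2.49 for Bglap3 (interval -5.54 to -0.62). Their calls were lost without section 1 for Etnk2 (-2.01), Bglap3 (-2.02) and Zscan22 (-1.76), without section 2 for Olfm3 (-2.68), Fam124a (-2.08), Etnk2 (-1.95) and Bglap3 (-1.86), and without section 4 for Etnk2 (-2.12).

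Plasma cell and immunoglobulin genes were higher in 15 of 15 in lymphoid spots (15 adjusted over the list alone; camera adjusted p = 3.41e-35, adjusted p = 0.104 with an estimated correlation). Mzb1, a plasma cell chaperone, was at 4.42 ± 0.08. All 10 class II genes were higher (10 adjusted over the list alone; camera adjusted p = 5.32e-18, adjusted p = 0.104 with an estimated correlation). Macrophage markers were higher in 17 of 19 with 1 lower (17 and 1 adjusted over the list alone; camera adjusted p = 1.08e-11, adjusted p = 0.177 with an estimated correlation). All 8 genes of lymphoid aggregates were higher (8 adjusted over the list alone; camera adjusted p = 5.45e-10, adjusted p = 0.135 with an estimated correlation), including Ccl19, a chemokine of T cell zones (3.03 ± 0.11). Interferon-gamma-induced genes were higher in 12 of 15 (13 adjusted over the list alone; camera adjusted p = 1.80e-08, adjusted p = 0.226 with an estimated correlation), led by Cxcl9 (3.02 ± 0.16). Type I interferon genes were higher in 11 of 19 (11 adjusted over the list alone; camera adjusted p = 1.70e-06, adjusted p = 0.104 with an estimated correlation). All 15 proliferation genes were higher (15 adjusted over the list alone; camera adjusted p = 2.25e-09, adjusted p = 0.104 with an estimated correlation). Mki67 was at 2.26 ± 0.22. Urothelium markers were higher in 5 of 6 (5 adjusted over the list alone; camera adjusted p = 1.46e-06, adjusted p = 0.104 with an estimated correlation), with Upk3a at 3.78 ± 0.13. Red blood cell genes were higher in 5 of 6 (5 adjusted over the list alone; camera adjusted p = 2.99e-06, adjusted p = 0.226 with an estimated correlation). Lower were 26 of 26 oxidative phosphorylation genes (26 adjusted over the list alone; camera adjusted p = 3.26e-17, adjusted p = 0.104 with an estimated correlation). Markers of the first proximal segments were lower in 13 of 15 (14 adjusted over the list alone; camera adjusted p = 3.86e-12, adjusted p = 0.104 with an estimated correlation).

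The test passed 3886 of 12204 genes, 1985 higher and 1901 lower in lymphoid spots. Among cortex zone spots alone it passed 172. In the 3 spatial comparisons 61 list tests passed with the preset correlation, 0 with an estimated one (30 at an unadjusted p under 0.05) and 66 by fry.

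Genes that changed with age in whole kidney were then looked up in the sections, which are other samples. B and T cell markers, which chose the lymphoid spots, rose with age too, so part of an excess there follows from that choice. Glomerular spots were chosen by markers too, and part of an excess there may follow from that choice. A gene could also be tested through its level in the lymphoid or the glomerular spots alone. Of the 1569 genes that rose at least 2-fold from 10 to 30 weeks 1003 could be tested in the lymphoid comparison, and 649 of them (64.7%) were higher in lymphoid spots, against 11.9% of other genes (camera adjusted p = 3.77e-39, adjusted p = 0.0471 with an estimated correlation). In glomerular spots 162 of 583 (27.8%) were higher, against 2.89% of other genes (camera adjusted p = 2.89e-28, adjusted p = 0.0770 with an estimated correlation). In the medulla zone 29.9% were higher, against 23.4% (camera adjusted p = 0.0237, adjusted p = 0.115 with an estimated correlation). That call was lost without section 3 (0.0714) or 4 (0.0729). Genes that fell with age were lower in lymphoid spots in 137 of 343 (39.9%, others 14.9%; camera adjusted p = 3.95e-11, adjusted p = 0.0104 with an estimated correlation). A smaller share of lymphoid than of other spots lay in the cortex zone, and the lookup was not repeated among cortex zone spots alone. In glomerular spots 42 of 211 were lower (19.9%, others 4.21%; camera adjusted p = 5.75e-08, adjusted p = 0.0770 with an estimated correlation). Between the zones they went both ways: 39.7% were higher in the medulla zone and 35.9% lower, against 23.4% and 20.4% of other genes, so that the set had no common direction (camera adjusted p = 0.686). Mmp7, among the largest rises with age (7.40 ± 0.99), was also among the genes highest in lymphoid spots over others (4.96 ± 0.45).

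**Figure D4:**
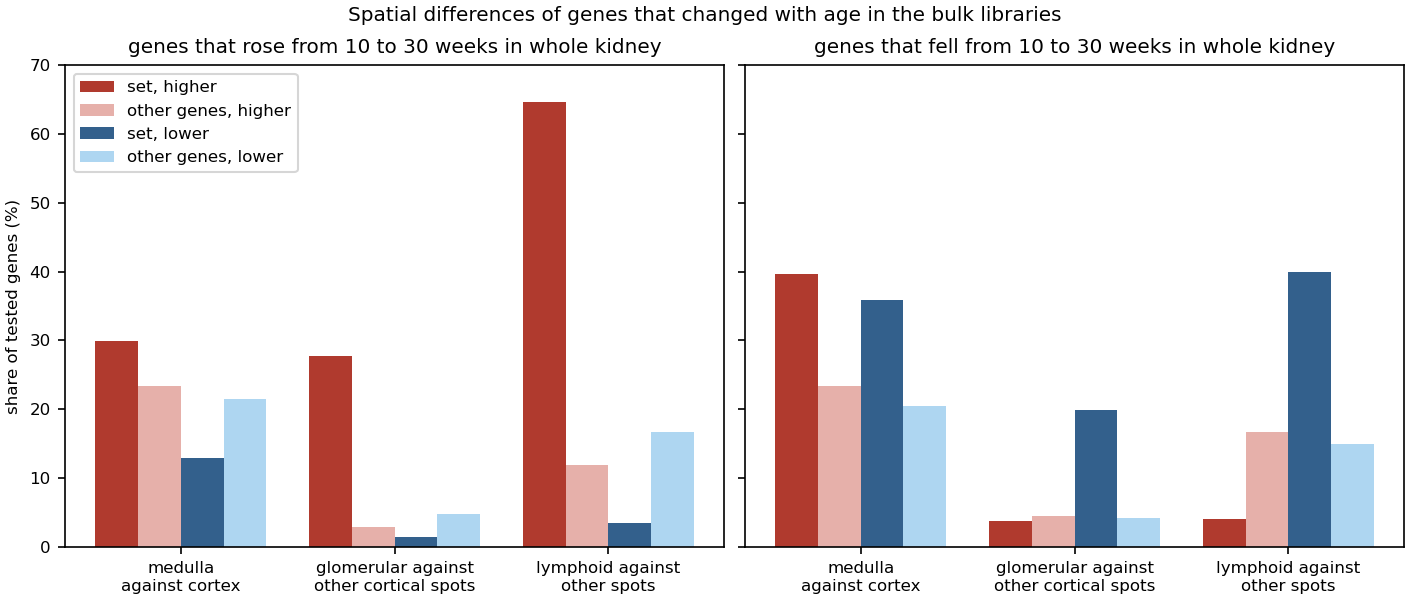
Share of tested genes (%) higher or lower in each spatial comparison, for genes that changed at least 2-fold with age in whole kidney and for all other genes. Of the genes that rose with age, 64.7% are higher in lymphoid spots and 27.8% in glomerular spots, against 11.9% and 2.89% of other genes.

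The authors' deposited spatial tables rank genes by Moran's I, which is high where neighbouring spots have similar levels. Among the 50 highest of every section in the authors' deposited tables were 32 shared genes, and among the 100 highest 63. Kap, which encodes a kidney androgen-regulated protein, had a mean Moran's I of 0.603 ± 0.0219 (SD, n = 4 sections) and Gpx3, a secreted glutathione peroxidase, 0.597 ± 0.0370. The zone comparison placed them apart, with Kap higher (1.83 ± 0.08, log2 ± SE) and Gpx3 lower (-3.34 ± 0.08) in the medulla zone. Among the 20 genes first by their lowest rank were also Napsa, Aadat, Igkc, Umod, Scd1, Ighg2c, Slc34a1, Ighg2b, Mpv17l, Serpina1f, Igha, Miox, Slc27a2, Scgb1c1, Pck1, Wfdc15b and Klk1. Of the 32, 7 were in the plasma cell and immunoglobulin list, 4 among markers of the first proximal segments, 2 among markers of the last proximal segment, 2 among thick limb markers and 2 in the gluconeogenesis list.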

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

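Among the tests below, those of time of day, of a smaller proximal tubule share and of entering leukocytes were chosen only after the result was seen. Of 75 sets of 4 section values looked at, 5 had a section far from the other ones, against about 5% of sets by chance. Clic3 in glomerular spots had a log2 ratio of 1.64 in section 4 and 2.35 to 2.49 in the others, and Gfra1 -4.32 in section 4 and -1.11 to -0.46 in the others. In lymphoid spots Frmd8os was at -1.54 in section 2 and -4.22 to -3.79 elsewhere, and Etnk2 at -0.25 in section 3 and -4.39 to -3.95 elsewhere, but these genes rest on 1 and 2 counts in all lymphoid spots. Moran's I of Napsa was 0.579 in section 1 and 0.527 to 0.533 in the others, in the authors' deposited tables.

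The change per interval differed for 2055 genes by a test of the difference itself. Of 100 splits of the 9 libraries 5 gave as many, the highest 5747, so chance cannot be excluded at a share under 0.05. The other 4 of these splits all keep the 30-week libraries together, and in the 95 splits that break them up the highest count was 3, which points to the 30-week libraries as the structure. For any difference among the 3 ages, 2 of 100 splits gave as many as the real 5000 genes (highest other 5303), a share under 0.05, so chance can be excluded for these splits. They do not keep any pairing of 10- and 20-week libraries by number. Of the 4 other splits that keep the 30-week libraries together 1 gave as many, and the 95 that break them up gave at most 1, so this count says little about 10 against 20 weeks.

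Between pairs of ages 10 splits are too few for a share under 0.05. The real count and the highest other were 1 and 0 genes for 20 against 10 weeks, 5047 and 1 for 30 against 10 weeks, and 5159 and 0 for 30 against 20 weeks. For lists called they were 13 and 18 (4 splits gave as many), 28 and 30 (3 splits) and 28 and 26 (1 split). These list counts were adjusted within each pair of ages alone. They therefore differ from the 68 list tests that passed when adjusted over all 3 pairs, and hold only under their own adjustment. In the sections 1 of 32 splits, the real one, gave as many genes; the real count and the highest other were 5235 and 0 for the zones, 856 and 101 for glomerular spots, and 3886 and 0 for lymphoid spots. The spot sums are paired by section, and 8 of these splits part every pair as the real one does, which are too few for a share under 0.05; the highest other among them was 0, 7 and 0. The remaining splits put both sums of some sections on one side. No split chooses the spots anew, so these counts do not show how much of a difference follows from that choice.

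At 30 weeks tubule genes were lower and immune and matrix genes higher than at 10 weeks. A smaller proximal tubule share as the whole cause would raise the markers of all other kidney cells alike, but distal tubule markers had a median log2 change of -0.97 with 6 of 9 falling. Leukocytes entering the kidney as the whole cause would not raise matrix genes that leukocytes lack, but Col1a1, Col1a2, Col3a1, Col6a1, Loxl1 and Fbn1 had a median of 2.92 with 6 of 6 passing. Either may be part of the cause, and age itself, disease and any batch shared by an age group stay open, untested.

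Per1 was lower at 20 than at 10 weeks, and the clock list shifted down (camera adjusted p = 0.000556, adjusted p = 0.242 with an estimated correlation) with no other member passing over all genes in edgeR. A difference in time of day of collection may be a cause: clock genes of the opposite phase had a median log2 change of 0.71, 4 of 4 above 0, while day-phase genes had -0.54, 9 of 10 below 0. For 30 against 10 weeks the medians were 0.14, 3 of 4 above 0, and -0.60, 8 of 10 below 0. Lower glucocorticoid signalling may be a cause too, since glucocorticoid-induced genes had a median of -0.57, 8 of 8 below 0, though 0 of 8 passed without the replicate block. Tsc22d3 among them passed in edgeR with the replicate block (adjusted p = 0.0344) and not without it (adjusted p = 0.433). Per1 responds to both, and no test here separates them. Age itself also stays open, untested. These small lists were not put through the splits, and the other list results over these weeks could not be told from an arbitrary grouping.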

How the results depend on the processing

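The fit with a replicate block on the libraries of 10 and 20 weeks alone was chosen after seeing the data. Over all alternatives, named genes kept direction and side of the threshold in 1805 checks and lost their call in 59, none reversing; lists kept both in 1768, lost their call in 179, gained one in 83 and reversed in 3. Counts of calls stayed within 1.5 times in 121 checks and moved further in 28. The cause was not tested unless given.

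For 20 against 10 weeks the count of 1 became 73 with DESeq2, 8 without the low-count filter, 4 with the replicate block, 3 on the libraries of these ages alone, 7 with both, and 0 to 9 without single libraries. Stricter thresholds gave fewer genes by construction: 2414 at 2-fold and 2875 at an adjusted p under 0.01 for 30 against 10 weeks, 2505 and 3103 for 30 against 20 weeks. Without single libraries the counts were 3474 to 5904 and 3686 to 5164 for these, 3287 to 5635 for any difference among ages and 786 to 2471 for the difference between intervals. The replicate block, applied to all 9 libraries although the numbers did not pair the 30-week ones, gave 4507, 4619, 4299 and 1504 genes for these 4 tests. The shared calls against 10 weeks went from 0 to 35 with DESeq2.

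DESeq2 gave 3231 genes for the zones and 354 for glomerular spots, and no block 445 for the latter. Without single sections the counts were 4219 to 5021, 390 to 729 and, for lymphoid spots, 3153 to 3511. Lymphoid spots chosen anew among cortex zone spots only, a smaller sample that takes in other spots, gave 172. The 100 highest in every section shared 63 genes.

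An estimated correlation left 0 bulk lists, 0 spatial lists and 2 age sets; single libraries or sections left out gave 66 to 79, 60 to 65 and 4 to 5, and the replicate block 71 bulk lists. The block gained the adipose list for 30 against 10 weeks (0.0443) and the neutrophil (0.0497) and dendritic cell (0.0399) lists for 30 against 20 weeks, and Slc12a1 lost its call for 30 against 20 weeks (-0.72); apart from the genes for 20 against 10 weeks it changed no other call of a named gene or list. For 20 against 10 weeks the oxidative phosphorylation list reversed without 20-week replicate 2 (0.0422; range without single libraries 0.00136 to 0.982), the gluconeogenesis list without 20-week replicate 3 (0.782; 0.000178 to 0.782) and the urothelium list without 10-week replicate 3 (0.0399; 0.00236 to 0.975).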

Other observations

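The comparison within single sections was chosen only after the result over pairs of sections was seen. Whether the 4 sections are adjacent sections of one kidney cannot be told apart from separate kidneys. If they were, maps of the glomerular score were predicted to match better than mirrored copies by at least 0.1 in all 6 pairs of sections. The largest excess was 0.0191, with 3 of 6 pairs better than mirrored. The bound written beforehand for separate kidneys was wrong, because the UMIs of one section dealt at random into a pair of sets, which do share their layout, also gave only -0.0326 to 0.0981, with 0 of 4 reaching 0.1.

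Skeletal muscle genes were detected in the sections. In the medulla and the cortex zone Ckm averaged 154 and 39.9 CPM, Acta1 170 and 54.7 CPM and Tnnt3 138 and 41.1 CPM, and 9 of 9 tested members of the list were higher in the medulla zone (9 adjusted over the list alone; camera adjusted p = 1.72e-09, adjusted p = 0.226 with an estimated correlation).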
